A study of Homo sapiens with 20 samples.

How the data were processed

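Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was measured in human large pulmonary artery endothelial cells, which are primary cells, grown for 48 hours in contact with smooth muscle cells of the same artery. The endothelial cells had received a control small interfering RNA (siControl) or one against PFKFB3 (siPFKFB3). PFKFB3 is an enzyme that makes fructose 2,6-bisphosphate, an activator of glycolysis. The antibodies were against Notch1, a cell-surface receptor whose cleaved part enters the nucleus, against p300, a histone acetyltransferase, and against H3K27ac, histone H3 acetylated at lysine 27, a mark of active promoters and enhancers. The 20 samples fell into 10 groups of 2 replicates each, with 12 ChIP samples and 8 input samples. The p300 samples and their inputs came from cells at passage 6 and the others from passage 7, so that comparisons of p300 with the other antibodies also compare passages. Cells were fixed with 1% formaldehyde, per the labels' protocols.

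Bowtie2, MACS2 and the genome build hg19 are named in the submitters' processing notes, with no version. The values came from 6 deposited lists, 1 for each antibody and siRNA. Per the file headers, each entry of a list is a peak in one replicate paired with a peak in the other, with the position and a significance value of each and an irreproducible discovery rate (IDR), a fraction that rises as the replicates' ranks of a peak diverge. Peaks were therefore called per sample, and a peak found in 1 replicate alone is absent from a list. The significance value of the deposited lists was read as −log10 of a p-value or q-value, because the smallest values in 4 of the lists lie just above 2; which of them it is was not stated. No limit on IDR had been applied to the deposited lists, whose largest IDR per list lay between 0.222 and 0.656. The headers do not say which replicate number a column belongs to, so the columns are called first and second. The input samples enter only through the authors' peak calling. The depth of each sample is unknown, since the lists hold no read counts.

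Each pair was represented by the interval that spans both replicates' peaks. Its strength was the mean of its percentile ranks in both columns within its own list, and strengths were never compared between lists. Pairs whose peaks lay on 2 different sequences were left out (7 and 5 in the siControl and siPFKFB3 Notch1 lists, 85 and 112 for p300, 10 and 3 for H3K27ac), as were 162 and 153 p300 pairs on unplaced or alternate sequences, and chromosome Y was not analysed. These choices were made after the lists had been examined. The Notch1 and H3K27ac lists held 0 pairs with both peaks on the same unplaced or alternate sequence. A difference in processing between p300 and the other antibodies can therefore not be excluded. The main comparisons of conditions and of antibodies, the matching on strength, the numbers of regions to name and most alternatives were fixed before the data were examined. The named regions were ranked by the strength above, so their choice was not fully fixed beforehand. Not among the fixed comparisons were the shares by strength decile and the siPFKFB3 peaks at sites of all antibodies. The class at both Notch1 and p300 and the split by p300 partner were not fixed either. Positions are hg19 coordinates as deposited; whether a start counts from 0 or 1 was not stated. Cytogenetic bands and chromosome lengths came from the hg19 tables of the R packages circlize and GenomeInfoDb. A region is called repeat-rich where it lies in a centromeric, variable heterochromatic or stalk band, within 1 Mb of a centromeric band, or within 50 kb of a chromosome end. Repeats elsewhere, such as tandem arrays on chromosome arms, were not marked.

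Overlaps of at least 1 base were found with bedtools 2.31.1, and the rest was computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. A peak with a partner is one that overlaps a peak of the same antibody in the other condition. Shares have exact 95% Clopper-Pearson intervals, which cover counting error over peaks and not the spread between replicates. Peaks are not replicates and each condition has 1 list per antibody, so no p-value for a difference between conditions was computed. Overlaps of 2 antibodies were set against 1000 random circular shifts of the first list within chromosomes. Shares kept among H3K27ac peaks at Notch1 or p300 peaks were set against 10000 random sets of the same size drawn from the same 10 strength deciles. The scripts were tested on simulated data over the 42533 control H3K27ac peaks. Planted shares were recovered with an error of at most 0.0094 percentage points. The planted peaks were slightly moved control peaks, so this checks the overlap code only. A planted excess of 10 percentage points in a set of 700 peaks was found in 20 of 20 simulations, and a set without excess lay between the 5th and 95th percentile of its random sets in 17 of 20. These simulated peaks were kept independently and by decile alone. Smaller excesses, strength differences within a decile and dependence between neighbours were not simulated.

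The named regions are, for each antibody, the 10 strongest siControl peaks without a partner, the 10 strongest siPFKFB3 peaks without a partner, the 5 strongest siControl peaks with one, and the 10 strongest siControl Notch1 peaks that overlap both p300 and H3K27ac. Alternatives were a reciprocal overlap of 50%, a gap of up to 500 bases, the strongest 50% of each list, equal list lengths and merging of peaks within 1 kb. Those added after the lists had been seen were an IDR of at most 0.05, each column's intervals alone, exclusion of repeat-rich regions, and matching on strength and width together. A comparison planned for 13 lists of 273 genes at their promoters was not run, because it needs gene positions on hg19, which were not used here. For the same reason peaks are named by position and band, and peaks at PFKFB3, NOTCH1 and EP300 are not reported.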

Results

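Peaks of Notch1, p300 and H3K27ac were compared between pulmonary artery endothelial cells with control siRNA and those with PFKFB3 silenced, 2 replicates per antibody and condition, all after contact co-culture with smooth muscle cells. The lists held only peaks paired across both replicates. H3K27ac had 42533 paired peaks over 45.9 Mb in siControl cells and 18306 over 18.7 Mb in siPFKFB3 cells. p300 had 16880 over 8.81 Mb and 14065 over 6.66 Mb. Notch1 had 2192 over 1.18 Mb and 1563 over 0.874 Mb. The replicate columns differed most in the siPFKFB3 H3K27ac list, where the median −log10 significance was 8.74 in the first column and 45.4 in the second, and the median peak widths were 441 and 934.5 bases. In the siControl H3K27ac list these medians were 13.0 and 19.1, and in the Notch1 and p300 lists the medians of both columns lay between 3.97 and 6.94. The Spearman correlation of both columns, taken across peaks, which are not independent replicates, was 0.779 for siControl and 0.444 for siPFKFB3 H3K27ac, 0.539 and 0.494 for p300, and 0.244 and 0.227 for Notch1.

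**Figure D1:**
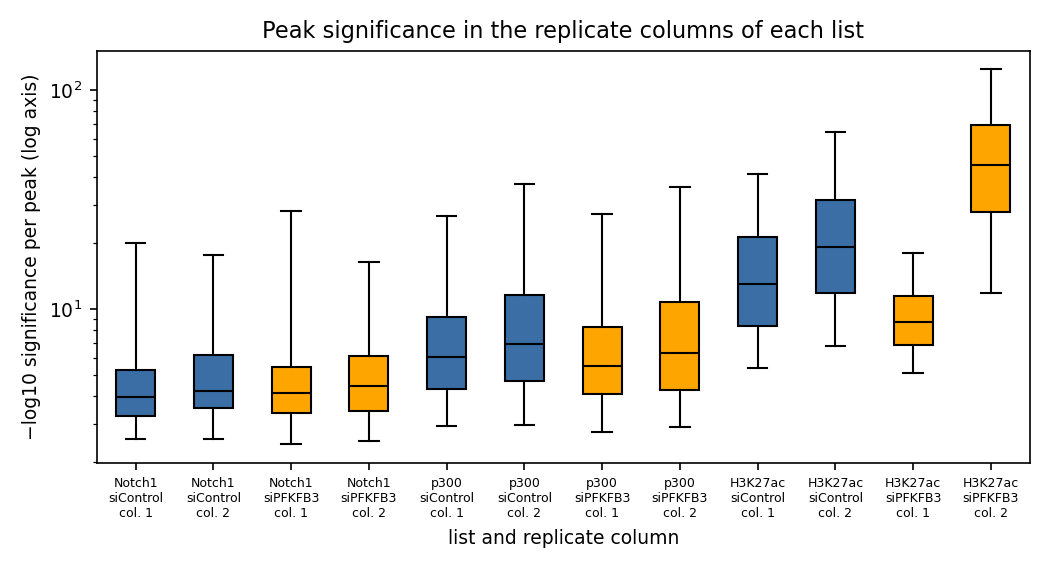
The −log10 significance of each peak (log axis) in the first and second replicate column of each of the 6 lists. Boxes span the quartiles with the median as a line, and whiskers reach the 5th and 95th percentiles; in the siPFKFB3 H3K27ac list the median is 8.74 in the first column and 45.4 in the second.

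The first question was how far H3K27ac, the mark of active promoters and enhancers, occupied the same regions in siControl and siPFKFB3 cells. Of the 42533 siControl H3K27ac peaks, 17065 had a siPFKFB3 partner, a share of 40.1% (95% interval 39.7 to 40.6), and 25468 had none. The siPFKFB3 list was almost contained in the siControl list: 17683 of its 18306 peaks, or 96.6%, had a siControl partner and 623 did not. The share of siControl peaks with a partner rose with strength, from 5.71% in the weakest decile to 90.5% in the strongest.

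Of the 10 strongest siControl H3K27ac peaks without a partner, 0 were near a centromere or at a chromosome end. Whether they lay in repeats of the chromosome arms was not examined. Of these 10, 4 lay close together in Xq23, between positions 114981436 and 114999725 of chromosome X, while the peak at 115004469 to 115005297 of the same band was among the 5 strongest with a partner. The pair of peaks in 17p11.2, at 18964504 to 18965307 and 18967341 to 18967769 of chromosome 17, had −log10 significances of 76.6 and 152.5 (first and second column) and of 80.6 and 177.3. The others lay in 11p15.5 (842112 to 842968), 19p13.3 (1020249 to 1021585), 19q13.2 (41869488 to 41870750) and 17p13.1 (8076547 to 8077658). The strongest siControl peaks with a partner included a pair in 1p36.13, a band known to carry U1 small nuclear RNA genes, at 16993303 to 16994020 and 17066434 to 17067128 of chromosome 1. A further pair of the 5 was near a centromere, in 10q11.21 (42529081 to 42529771) and 8p11.1 (43793214 to 43794178).

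Of the 10 strongest siPFKFB3 H3K27ac peaks without a siControl partner, 2 were at chromosome ends and 3 near centromeres. The strongest was at the end of the long arm of chromosome X (Xq28, 155259975 to 155260447), followed by the start of chromosome 1 (1p36.33, 28738 to 29377) and by 1p36.21 (15851066 to 15851371). Those away from repeat-rich regions also included 17q24.1 (62658044 to 62658430), 20q13.13 (47804384 to 47804907) and 4p15.32 (16227725 to 16228945). Repeat-rich regions held 7.54% of the 623 siPFKFB3 peaks without a partner and 2.27% of those with one. With the siControl list shortened to its 18306 strongest peaks, 69.0% had a partner. Of the 28444 siControl peaks with an IDR of at most 0.05, 15447 or 54.3% had a partner in the whole siPFKFB3 list, and 11.1% had one among the 3203 siPFKFB3 peaks under the same limit, a share bounded by the length of that list, since 99.0% of those 3203 had a siControl partner.

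**Figure D2:**
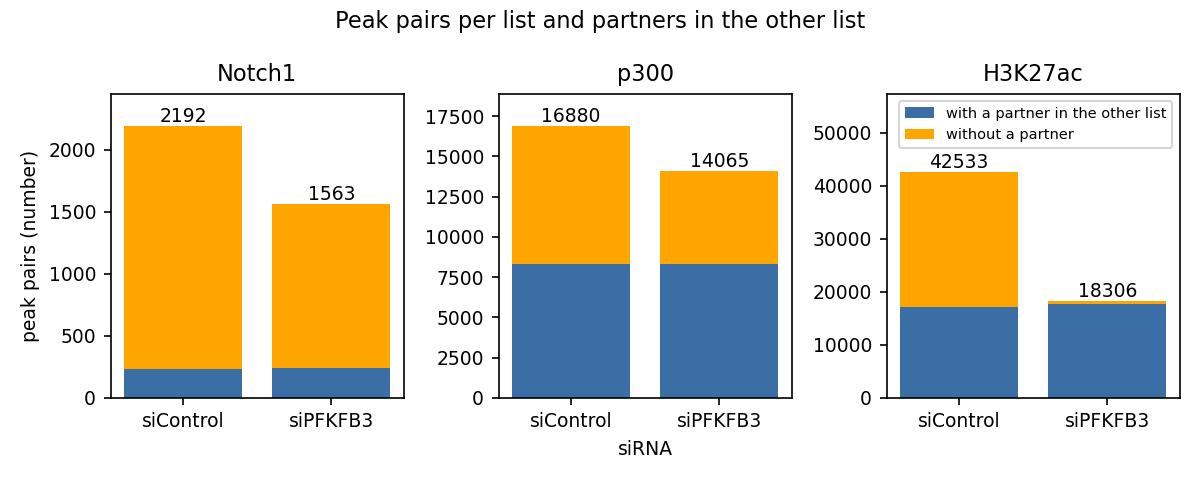
Number of paired peaks in each list (vertical axis, its own scale for each antibody) for siControl and siPFKFB3 cells, split into peaks with a partner in the other condition and peaks without. In siPFKFB3 cells 17683 of 18306 H3K27ac peaks have a partner, against 17065 of 42533 in siControl cells.

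For p300, an acetyltransferase known to place this mark, the lists of both conditions were closer in length and neither contained the other. Of 16880 siControl p300 peaks, 8296 had a siPFKFB3 partner, or 49.1% (48.4 to 49.9), and 8338 of 14065 siPFKFB3 peaks, or 59.3% (58.5 to 60.1), had a siControl partner. The strongest p300 peaks were present in both conditions: 98.5% of the strongest siControl decile had a partner, against 17.7% of the weakest, and 91.7% of the 3206 siControl peaks with an IDR of at most 0.05 had one. The strongest shared peaks were at 8q13.1 (67025342 to 67026792, −log10 significances 417 and 457), 14q11.2 (23398354 to 23399207), 1q42.13 (228750215 to 228750904), 1q44 (249167717 to 249168803) and 16p13.3 (3200360 to 3201158). The band 1q42.13 is known for its array of 5S ribosomal RNA genes.

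The 10 strongest p300 peaks of each condition without a partner differed in how many lay near a centromere. In siControl cells 0 of the 10 strongest without a partner were near a centromere, and the first of them were in 14q11.2 (21125376 to 21125846, −log10 significances 25.7 and 106.4), 7q36.1 (149028094 to 149028412) and 19p13.3 (1940529 to 1941013). The list went on with 12q14.1 (59151101 to 59151566), 14q32.2 (100070611 to 100071032), 2q22.1 (136993583 to 136994153) and 6p22.1 (27529841 to 27530173). In siPFKFB3 cells 9 of the 10 were near a centromere, 5 of them between 92305583 and 92321908 in 2p11.1, and the exception was in 17q24.3 (68030266 to 68030760). Whether the p300 peaks near centromeres reflect binding was not examined. Over the whole lists, repeat-rich regions held 1.92% of the siControl and 3.13% of the siPFKFB3 p300 peaks without a partner, and 4.65% and 4.67% of those with one.

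Notch1 peaks were few, and most had no partner in the list of the other condition. Only 235 of 2192 siControl peaks had a siPFKFB3 partner, or 10.7% (9.46 to 12.1), and 237 of 1563 siPFKFB3 peaks, or 15.2% (13.4 to 17.0), had a siControl partner. In the strongest siControl decile 51.6% (44.8 to 58.4) had a partner, and in the weakest 0.455% (0.0115 to 2.51). The shared peaks lay more often in repeat-rich regions: 33.2% of the siControl Notch1 peaks with a partner did, against 6.03% of those without.

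The strongest Notch1 peak found in both conditions was in 2q37.3 (chromosome 2, 241259542 to 241260219), with −log10 significances of 104.4 and 27.7 in siControl cells. It was followed, in order, by 3q29 (193858583 to 193859387, 64.7 and 24.9), by 8p11.1 (43822269 to 43822617) and Xq11.1 (61712478 to 61712769), both near centromeres, and by 7q22.3 (105128218 to 105128680, 101.3 and 18.5). All 10 of the strongest siControl Notch1 peaks without a partner were near centromeres, 4 of them in Xq11.1 between 61695718 and 61718029, and so were 9 of the 10 strongest siPFKFB3 ones. The exception was in 10q24.32 (103124564 to 103124778), whose significance was 10.6 in the first column and 50.7 in the second. The strongest siControl Notch1 peak without a partner (Xq11.1, 61717777 to 61718029) overlapped a siPFKFB3 H3K27ac peak without a siControl partner (61717783 to 61718033). Whether the Notch1 peaks near centromeres reflect binding was not examined. In the strongest 50% of each list 18.98% of siControl peaks had a partner. The order of the list lengths turned at an IDR of at most 0.05, where 177 siControl and 217 siPFKFB3 Notch1 peaks were left, so these lists do not establish fewer Notch1 peaks after silencing.

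**Figure D3:**
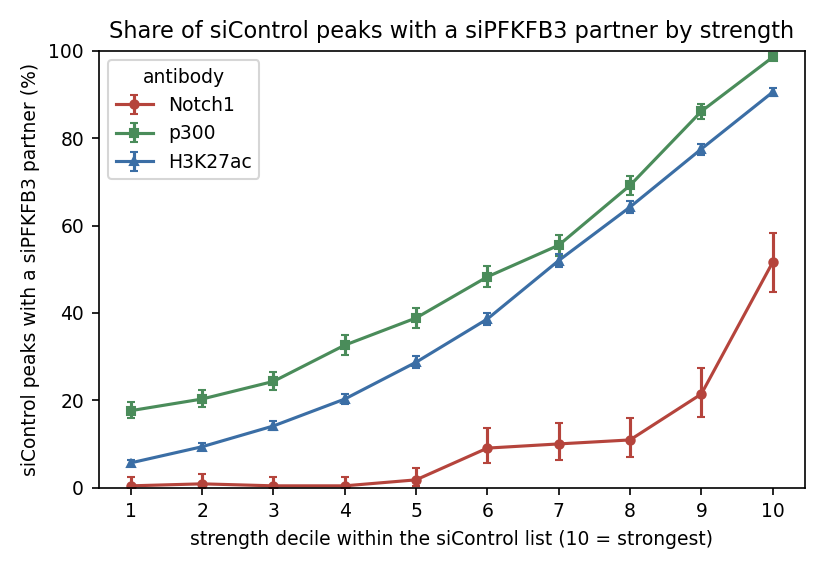
Percent of siControl peaks with a siPFKFB3 partner (vertical axis) by strength decile within the siControl list (horizontal axis, 10 the strongest), for Notch1, p300 and H3K27ac, with exact 95% intervals. The strongest decile reaches 98.5% for p300, 90.5% for H3K27ac and 51.6% for Notch1.

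The next question was whether the factors and the mark lay at the same regions within each condition. In siControl cells 72.7% (72.1 to 73.4) of p300 peaks overlapped an H3K27ac peak, and in siPFKFB3 cells 44.0% (43.2 to 44.8) did. Notch1 peaks overlapped p300 peaks in 26.3% (24.4 to 28.2) and 26.8% (24.6 to 29.1) of cases, and H3K27ac peaks in 30.3% (28.4 to 32.3) and 24.6% (22.5 to 26.8). All 6 shares were above each of the 1000 random shifts, whose means ran from 0.549% for siPFKFB3 Notch1 at p300 to 2.41% for siControl p300 at H3K27ac. The shifts move peaks over whole chromosomes. Lists that gather at the same kinds of regions would exceed them without a specific link between the antibodies. The overlaps of p300 with the others join cells of different passages. With the siControl H3K27ac list shortened to the length of the siPFKFB3 list, the p300 share was 52.1% against 44.0%, and the Notch1 share was 22.5% against 24.6%, which turns the order of the conditions for Notch1. At an IDR of at most 0.05, which left 28444 siControl and 3203 siPFKFB3 H3K27ac peaks and so limits the siPFKFB3 shares, 70.6% and 12.9% of p300 and 27.7% and 9.68% of Notch1 peaks lay at H3K27ac in siControl and siPFKFB3 cells. Under a reciprocal overlap of 50% the shares at H3K27ac were 14.1% and 8.14% for p300 and 7.07% and 8.19% for Notch1 in siControl and siPFKFB3 cells, and those of Notch1 at p300 were 15.5% and 17.1%.

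**Figure D4:**
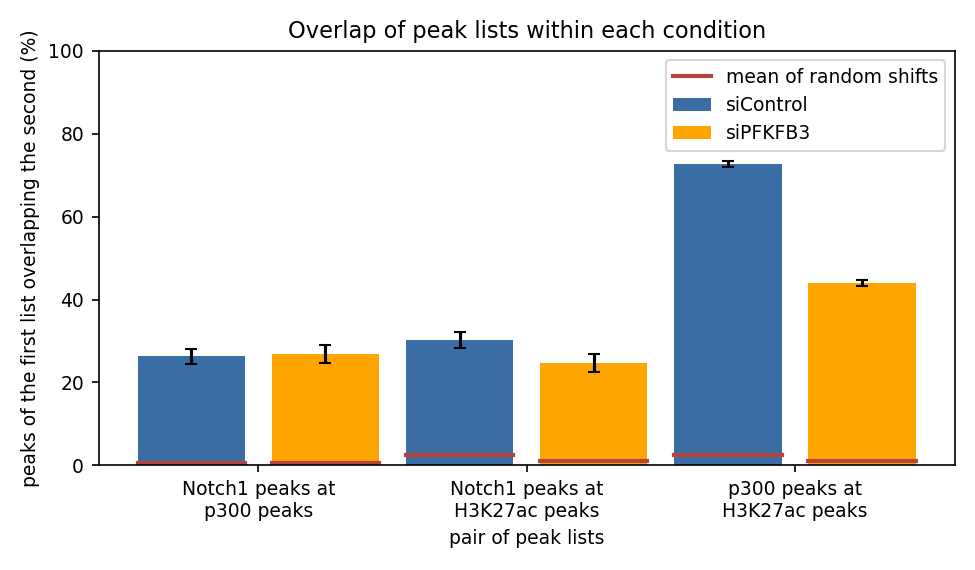
Percent of the peaks of the first-named list that overlap the second-named list (vertical axis) in siControl and siPFKFB3 cells, with exact 95% intervals; red lines are the means of 1000 random shifts. The p300 share at H3K27ac is 72.7% in siControl and 44.0% in siPFKFB3 cells.

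Notch1, p300 and H3K27ac peaks coincided at 433 siControl Notch1 peaks, or 19.8% of that list, and at 257 siPFKFB3 ones, or 16.4%. At the 433 siControl sites, siPFKFB3 cells had a p300 peak at 360, or 83.1% (79.3 to 86.5), an H3K27ac peak at 331, or 76.4% (72.2 to 80.4), and a Notch1 peak at 153, or 35.3% (30.8 to 40.0). All 3 were present at 118 sites, p300 and H3K27ac without Notch1 at 163, and none at 20. Over the whole siControl lists the shares with a partner were 49.1% for p300, 40.1% for H3K27ac and 10.7% for Notch1. These whole-list shares count each antibody's own peaks, whereas those at the 433 sites count Notch1 intervals. For p300 and H3K27ac the shares are therefore of unlike units. The 433 sites were not matched on strength, and the siPFKFB3 Notch1 list was the shortest of that condition. Of the 433 sites, 71 lay in repeat-rich regions, and of the 10 strongest, 7 were near a centromere. The other 3 of these 10 were 2q37.3, 3q29 and 7q22.3 at the positions given above, and each kept Notch1, p300 and H3K27ac peaks in siPFKFB3 cells. At the 4 centromere-near sites without a siPFKFB3 Notch1 peak, in 2p11.1 (92297862 to 92298168), 19q11 (27738339 to 27738663), 8p11.1 (43838498 to 43838759) and 8q11.1 (46855094 to 46855552), p300 and H3K27ac peaks were present.

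siControl H3K27ac peaks at Notch1 or p300 peaks had a siPFKFB3 partner more often than random sets from the same strength deciles. These sets were drawn from the whole siControl H3K27ac list with these peaks included. Of the 688 siControl H3K27ac peaks at a Notch1 peak, 483 had a partner, or 70.2% (66.6 to 73.6), where strength-matched random sets averaged 60.3% and reached at most 65.7%. Of the 12420 at a p300 peak, 7510 had one, or 60.5% (59.6 to 61.3), against a matched mean of 56.2% and a highest value of 57.2%. The 489 peaks at both Notch1 and p300 had the highest share, 75.5% (71.4 to 79.2), against 65.7% in matched sets. The 29914 H3K27ac peaks at neither had a share of 31.6% (31.0 to 32.1) (matched mean 33.4%, which lies above it by construction once the factor-bound peaks of the same list exceed theirs). Without matching, the excess was 30.1 percentage points at Notch1 and 20.3 at p300 peaks, against 9.87 and 4.29 with matching on strength. Matching on width alone gave 23.3 and 12.7 points, and a reciprocal overlap of 50% gave 2.497 points at p300 peaks. No random set was matched on repeat-rich regions or on strength within a decile. Repeat-rich regions held 2.23% of the siControl H3K27ac peaks with a partner and 1.25% of those without. The cause of the excess at Notch1 peaks therefore stays open.

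Within the H3K27ac peaks at p300, those at a p300 peak present in both conditions had a partner in 61.5% of 7103 cases (matched mean 58.7%), and those at a siControl p300 peak without a partner in 59.0% of 5317 cases (matched mean 52.8%). Seen from the factor, p300 peaks at an H3K27ac peak with a partner were themselves kept in 56.0% of 8029 cases, above their strength-matched mean of 52.0%. p300 peaks at an H3K27ac peak without a partner were kept in 50.2% of 4248 cases (matched mean 49.6%), and p300 peaks outside H3K27ac in 36.3% of 4603 (matched mean 43.7%). For Notch1 the same 3 classes were kept in 28.1% of 484, 18.3% of 180 and 4.32% of 1528 peaks, against matched means of 18.7%, 13.3% and 7.90%. The 3 classes divide each factor's list, and the random sets are drawn from that whole list. The shares below the matched mean outside H3K27ac therefore follow by construction from those above it at H3K27ac. This division of the factor peaks was added after the lists had been seen.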

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

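The tests of a weak replicate column, of Notch1 peak strength, of Notch1 peaks with a low IDR and of matching on strength and width together were chosen after the results had been seen. For list length, the alternative of equal lengths was planned, but its use as a test was chosen after the results had been seen.

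Pairs whose replicate peaks lie on 2 different sequences numbered 112 in the siPFKFB3 p300 list and 85 in the siControl one; they were outside every comparison and stood above the level of the siControl list.

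Most siControl H3K27ac peaks (25468 of 42533) had no siPFKFB3 partner. How much of this comes from list length stays open: with equal lengths 69.0% of H3K27ac peaks had a partner, against 55.3% for p300 and 14.8% for Notch1, and these data hold no unchanged pair of lists to set beside them. A weak replicate may limit the siPFKFB3 list, since the first column held the lower value in 97.66% of its pairs; in the siControl list it did so in 80.4%. Each list holds only pairs, so the list without that replicate cannot be rebuilt, and a failure of the weaker replicate to call a peak looks the same here as loss of the peak. An effect of PFKFB3 silencing on H3K27ac stays open and untested.

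Few siControl Notch1 peaks (235 of 2192) had a siPFKFB3 partner. Whether these are weak peaks that do not recur stays open: 0.821% of those below the median strength had a partner, which a real change would give too. Of the peaks with an IDR of at most 0.05, 23.2% (17.2 to 30.1) had a partner, and no value here gives the share for unchanged lists. Repeats near centromeres and chromosome ends do not account for all shared peaks, because outside those regions 7.87% (6.72 to 9.14) still had a partner. Repeats elsewhere were not marked, so their part in the shared peaks stays open. A change in Notch1 binding after PFKFB3 silencing stays open and untested.

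siControl H3K27ac peaks at p300 peaks had a siPFKFB3 partner more often than random sets drawn from the whole siControl H3K27ac list. The values argue against differences between deciles of strength or width as the whole cause. The share exceeded every strength-matched set (mean excess 4.29 percentage points), every width-matched set (12.7) and every set matched on both (3.91). Matching by decile cannot exclude strength itself as the whole cause, because the share with a partner rose from 5.71% to 90.5% over the strength deciles. Whether the excess was larger where the p300 peak had no siPFKFB3 partner or where p300 was in both lists depended on the matching. It was 6.19 and 2.86 points with strength and 5.22 and 2.92 with both, but 11.5 and 13.7 with width and 18.9 and 21.4 without matching. Differences of strength within a decile, the weak siPFKFB3 column, the other passage of the p300 cells and a biological cause stay open and untested. The random sets were not matched on repeat-rich regions either.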

How the results depend on the processing

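The alternatives with an IDR of at most 0.05, with each column's intervals, without repeat-rich regions and with joint matching were chosen after the lists had been seen. Over 11 results and 73 alternatives, 17 values stayed within their interval, 3 siPFKFB3 overlaps at equal lengths could not move because that alternative leaves their lists as they are, and 53 moved beyond it. The order of siControl and siPFKFB3 for Notch1 at H3K27ac turned under reciprocal overlap and at equal lengths (22.5% against 24.6%). Where an alternative shortens the lists or asks for a tighter or looser overlap, the change follows partly from its construction; otherwise the cause was not tested.

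For siControl peaks with a siPFKFB3 partner (10.7% of Notch1, 49.1% of p300 and 40.1% of H3K27ac as reported), in that order of antibodies, a reciprocal overlap gave 8.94%, 39.9% and 32.9%, and a gap of up to 500 bases gave 12.2%, 52.4% and 44.1%. The strongest 50% of each list gave 18.98%, 56.2% and 40.9%, equal lengths gave 14.8%, 55.3% and 69.0%, and an IDR of at most 0.05 gave 15.3%, 56.0% and 11.1%. Merging gave 42.8% for H3K27ac. First-column intervals gave 47.5% for p300 and 39.4% for H3K27ac, and second-column intervals 48.3% for p300. Without repeat-rich regions Notch1 had 7.87%.

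For overlaps between antibodies, siControl and then siPFKFB3, Notch1 at p300 was 15.5% and 17.1% with reciprocal overlap, 29.8% and 30.3% with the gap, 34.9% and 35.2% in the strongest 50%, 29.4% and 33.6% at the IDR limit, and 22.9% and 22.4% without repeat-rich regions. Notch1 at H3K27ac was 7.07% and 8.19% with reciprocal overlap, 35.2% and 28.7% with the gap, and 27.7% and 9.68% at the IDR limit. It was 33.8% in the strongest 50% and 22.5% at equal lengths in siControl, and 21.4% without repeat-rich regions in siPFKFB3. p300 at H3K27ac was 14.1% and 8.14% with reciprocal overlap, 76.6% and 47.7% with the gap, 63.9% and 33.4% in the strongest 50%, and 70.6% and 12.9% at the IDR limit, and 52.1% in siControl at equal lengths.

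The excess of H3K27ac peaks kept at Notch1 peaks (9.87 percentage points) was 30.1 without matching and 23.3 with width matching. At p300 peaks (4.29) it was 20.3 without matching, 12.7 with width matching and 2.497 with reciprocal overlap.

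No paired analysis was possible because the headers do not tie the columns to replicate numbers. Lists without 1 replicate could not be computed either, since a peak found in 1 replicate alone is absent from them. The alternatives for promoters of gene lists were not run, as gene positions on hg19 were not used here. Read depth is unknown, so a missing peak cannot be told from one below detection.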

Other observations

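The divisions by cytogenetic band and by domain were all chosen after the lists had been seen, and they carry no planned test.

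The share of siControl H3K27ac peaks with a siPFKFB3 partner varied along the genome. Among 365 bands with at least 50 siControl peaks, 41 lay outside the middle 95% of strength-matched random sets, where 18.2 would by chance, although neighbouring peaks are not independent. Both bands above every one of the 10000 sets were neighbours on the short arm of chromosome 6. In 6p22.1, known for histone and transfer RNA gene clusters, 33 of 52 peaks or 63.5% had a partner (matched mean 39.0%, highest 61.5%). In 6p21.33, within the major histocompatibility complex, 41 of 60 or 68.3% had one (matched mean 42.4%, highest 63.3%). The 1 band below every set was 1q42.13, with 13 of 62 peaks or 21.0% (matched mean 40.1%, lowest 22.6%). By staining class, the darkest bands had 32.9% against a matched mean of 37.5% (middle 95% of sets 36.2 to 38.7) and the next darkest 35.8% against 38.1% (37.0 to 39.2). The lighter stained classes had 39.99% against 38.9% (37.9 to 39.8) and, for the lightest, 43.8% against 42.3% (41.1 to 43.4), and the unstained bands had 41.0% against 40.6% (40.3 to 40.9). These classes are parts of one list, so shares above and below the matched means follow partly from each other.

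siControl H3K27ac peaks within 10 kb were joined into domains. Peaks standing alone lay above the middle 95% of random siControl sets from the same strength deciles. Peaks in domains of 5 to 9 lay below it. The classes divide one list, so a share above the matched mean in one class requires shares below it in others. The random sets draw peaks independently, so their ranges do not cover the dependence between neighbouring peaks. Peaks standing alone, 18493 in number, had a partner in 43.4% of cases (matched mean 42.5%, middle 95% of sets 42.1 to 42.9). In domains of 2 to 4 peaks, 37.9% of 20437 peaks had a partner (matched mean 38.3%, 37.9 to 38.7). In domains of 5 to 9 peaks the share was 35.3% (matched mean 37.3%, 36.0 to 38.6), and in the 26 domains of 10 or more it was 43.5% (37.99 to 49.1), against a matched mean of 47.4% (43.2 to 51.6). Each of these 26 had at least 1 peak with a partner. The domain with the largest covered length, in 16q11.2 (46386067 to 46435552), is among these 26, is repeat-rich and had a partner for 19 of 20 peaks. Among the next in covered length, 5q35.1 (172285624 to 172359489) had 5 of 14, 10q24.32 (104357346 to 104406167) 6 of 9, 3q29 (194861675 to 194931977) 3 of 18 and 20q13.2 (49956018 to 50029212) 4 of 13. The domain in 17p11.2 (18934933 to 18997196), which spans both 17p11.2 peaks named among the strongest without a partner, had 3 of 13.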
